A study of Mus musculus with 4 samples.

How the data were processed

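The series holds single-cell RNA libraries of splenic B cells and of CD4+ T cells from mice with Il2rb deleted in B cells (KO) and from Cre control mice, unimmunized (day 0) or 4 days after intraperitoneal sheep red blood cells (day 4). Each of the 2 libraries pooled 4 populations marked by hashtag antibodies, and the series design text ties hashtag 1 to KO day 4, 2 to control day 4, 3 to KO day 0 and 4 to control day 0. The characteristics give the same genotype text for both genotypes, so genotype was taken from the hashtag text. The number of mice per pool is not given in the sources used here.

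The deposited matrices hold counts of unique molecular identifiers (UMIs) per cell for 32285 genes and 4 hashtags, made with Cell Ranger 5.0.0 on mm10 according to the submitters' processing notes. Gene positions came from GENCODE vM21 on the same build, which matched 32158 of 32285 gene identifiers (99.61%). The annotation release behind the matrices is not given in the sources used here.

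Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept, 6218 of 6339 in the B library and 9196 of 9307 in the T library. Hashtags were assigned with HTODemux of Seurat 5.3.0 (R 4.3.3) at its positive quantile of 0.99. This left 5477 B-library and 7636 T-library cells with 1 hashtag, besides 568 and 1007 cells with several and 173 and 553 with none. Cells with several hashtags were left out as doublets. Scrublet was also run, but its automatic threshold called 1 cell in the B library and 0 in the T library, so it removed no cells from the main results. Median UMIs of the own and of the next hashtag ranged from 1736 against 111 in T-library KO day 0 cells to 4469 against 57 in B-library control day 4 cells.

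Median depths in control day 0, KO day 0, control day 4 and KO day 4 were 4673, 4928, 6198 and 5923 UMIs in the B library and 4504, 4501, 5575 and 5449 in the T library. The groups summed to between 4749526 and 20482212 UMIs. The median absolute log2 ratio over genes was 0.11 to 0.19 in the B library and 0.09 to 0.18 in the T library, against 0.07 to 0.09 and 0.06 to 0.09 from counting error alone in 20 simulations of each comparison.

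Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 (10000 UMIs per cell, 2000 variable genes, 30 principal components, 15 neighbors, resolution 1.0), which gave 19 clusters in the B library and 18 in the T library. Genes of the level lists and receptor, ribosomal and mitochondrial genes were left out of clustering. A cluster took the name of its lineage's marker list with the highest median log2 fold, if that was at least 0.5 and at least 3 markers were higher and found in at least 10% of cells (Cd8a among them for CD8 T cells). No name was given where another list had more genes among the cluster's top 10 genes, or where none of its own was there and the median UMIs were under 1/3 of the library's. Clusters with pan-lineage markers under −2 or foreign markers of at least 2 on the log2 scale were called other lineages, except the plasma cell-like cluster, whose pan-lineage markers stood at −3.99. The other clusters kept numbers. Cell type lists covered follicular, marginal zone, transitional, B1, germinal center, plasma and atypical B cells, naive, regulatory, follicular helper, effector or memory, CD8 and NK or innate-like T cells, monocytes, neutrophils, dendritic and erythroid cells and cycling cells.

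Gene levels were summed UMIs per pool or class scaled to a common total (CPM), with exact Poisson intervals for levels, conditional binomial intervals for ratios and exact binomial intervals for shares, all at 95%. Each group was 1 pool, so there was no test and no p-value, and cells were not taken as replicates. KO was compared with control on each day, and day 4 with day 0 in each genotype, in each library. Cell classes were compared with follicular B-like or naive T-like cells, and B lineage with T lineage cells. There were 13 level lists, and a member counted with at least 20 UMIs in both sums together. A list's median log2 ratio was placed among 10000 random lists matched on mean expression. Where a sum was 0, a floor of 3 counts gave the limit. Shares of cells with a UMI were taken after thinning each cell to 1500 UMIs.

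Named genes were Il2rb, Il2ra and Il2rg, up to 3 highest and 3 lowest members of each list with an interval that excluded 1, members named to give a value that did not, and the 12 highest and 12 lowest genes with at least 100 UMIs and such an interval, without receptor variable genes. Some genes that meet the rule are not reported here. The lists, markers, filters, comparisons, rules for naming genes and some of the alternatives were fixed before the data were examined. As few cells of other lineages led many of the genes named by size, a further rule was added after seeing the data: lineage cells only, at most 10% of a gene's UMIs from 1 cell and UMIs in at least 2% of the cells of a pool.

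The ratio intervals were tested on simulated data in which genes of the KO day 0 against control day 0 comparison were given known folds. Counts were drawn independently for each gene with counting error alone. The simulations therefore do not show how intervals or list percentiles behave when UMIs lie in few cells or genes vary together. Of 8404 genes in the B library, 92.7% of those given a fold of 1.5, 98.4% at a fold of 2 and 100% at a fold of 4 had an interval on the right side of 1, and 4.27% of unchanged genes had one off 1. Of 7805 genes in the T library the values were 85.0, 100, 100 and 4.43%. For a list of 19 genes shifted by −0.3 on the log2 scale, 100 of 100 simulations fell below the random range in each library. With no shift, 3 fell below and 8 above it in the B library, and 3 and 4 in the T library.

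The alternatives tried were a hashtag ratio rule (at least 10 UMIs and 3 times the next), doublets kept, at most 5% mitochondrial UMIs, at least 500 genes, resolutions of 0.5 and 2.0, 3000 variable genes, list genes allowed in clustering, CPM without receptor, ribosomal and mitochondrial genes, mean per-cell CPM, members with at least 1 or 100 UMIs, and shares unthinned or thinned to 1000 UMIs. Lineage cells only, and cells without the highest Scrublet scores, were also tried. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9. Sequence reads were not analysed here.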

Results

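Splenic B cells and CD4+ T cells came from mice with Il2rb deleted in B cells (KO) and from Cre control mice, either unimmunized (day 0) or 4 days after sheep red blood cells (day 4). Il2rb encodes the beta chain shared by the interleukin-2 and interleukin-15 receptors. After filtering, 5477 cells of the B library and 7636 cells of the T library carried 1 hashtag. In the order control day 0, KO day 0, control day 4 and KO day 4, the pools held 1126, 1019, 1393 and 1939 B-library cells and 1005, 1325, 2048 and 3258 T-library cells. Each group was 1 pool without replicates, so no difference between groups was tested, and every interval is a 95% interval of counting error only. A list's median is given with its percentile among 10000 random lists matched on expression, as a description of these libraries. A median over a whole pool depends on its mix of cell classes, so medians within classes are given beside some. Classes came from clustering, so cells that changed state could leave a class, and medians within it do not cover them.

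Il2rb, the deleted gene, was close to absent from B cells of every group. Cells of the B lineage held 0 Il2rb UMIs in 1101 control and 989 KO cells at day 0, under 3-count floors of 0.515 and 0.526 CPM (UMIs of a gene scaled to a common library total). At day 4 they held 9 Il2rb UMIs in 1319 control cells and 4 in 1875 KO cells, or 0.885 CPM (0.405 to 1.68) and 0.294 CPM (0.0802 to 0.754), with a KO over control ratio of 0.333 (0.0748 to 1.19). Over all 5284 B cells, 0.208% held an Il2rb UMI unthinned and 0.0571% (0.0118 to 0.167%) after thinning to 1500 UMIs, at a median depth of 5430 UMIs with 25 cells too shallow to thin. Cd79a, a B cell receptor component that T cells should lack, was counted in 0.454% of T lineage cells unthinned and 0.161% thinned, at a median depth of 5165 UMIs with 47 cells too shallow. Ms4a1, another B cell gene, had 1 UMI in T lineage cells, and Cd3e, a T cell receptor component, 0 UMIs in B lineage cells, so it is not settled whether the Il2rb UMIs of B cells are background. With 0 UMIs at day 0 and a day 4 ratio interval that included 1, the Il2rb level could not check the genotype labels in B cells. Counts were also 5′ tags, and the floxed exons of Il2rb, a minus-strand gene at 78479256 to 78495271 on chromosome 15, are not given in the sources used here. A tag outside the deleted part would not check the deletion. Over all assigned cells of the B library Il2rb stood at 3.60, 2.98, 1.12 and 1.998 CPM in the order above, and 70 of these UMIs lay in 193 cells of other lineages.

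In the T library, whose cells were not the target of the deletion, Il2rb stood at 85.9 CPM in control and 77.2 CPM in KO cells at day 0, and at 109 and 104 CPM at day 4. The KO over control ratios were 0.898 (0.787 to 1.03) and 0.953 (0.891 to 1.02). Over all T-library cells Il2rb was higher at day 4 than at day 0 in both genotypes, 1.27-fold (1.14 to 1.42) in control and 1.35-fold (1.22 to 1.49) in KO cells. These levels also depend on the mix of classes. Within regulatory, follicular helper and NK or innate-like T cells, with levels given at the end, Il2rb stood higher at day 4 only in control regulatory T-like cells. The other subunits of the receptor stood in B-library cells at 409, 371, 307 and 361 CPM for Il2rg, the common gamma chain, and at 3.13, 2.32, 2.16 and 2.14 CPM for Il2ra, the alpha chain.

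Among the named T cell classes, Il2rb was highest in NK or innate-like T cells, at 846 CPM (779 to 917), followed by 314 CPM (297 to 330) in regulatory T-like, 226 CPM (207 to 247) in effector or memory CD4 T-like, 146 CPM (136 to 157) in follicular helper T-like and 8.33 CPM (6.41 to 10.6) in naive T-like cells. After thinning to 1500 UMIs, an Il2rb UMI was found in 67.0% of NK or innate-like, 34.8% of regulatory, 26.4% of effector or memory, 17.7% of follicular helper and 1.35% of naive-like cells. Unthinned, these shares were 97.46, 64.2, 51.6, 61.2 and 3.77% at median depths of 5360, 4483, 4596, 9361 and 5161 UMIs, with 0, 11, 2, 1 and 3 cells too shallow. A background for these shares was not measured here. Il2ra stood at 296 CPM (280 to 312) in regulatory T-like cells, 112 CPM in NK or innate-like and 26.8 CPM in effector or memory cells, 7.33 CPM in follicular helper T-like and 4.16 CPM in naive-like cells. Il2rg ranged over the same classes from 430.1 CPM in naive-like to 709 CPM in NK or innate-like T cells. In the B library Il2ra was highest in transitional B-like cells, at 14.5 CPM (9.80 to 20.7), against 0.280 CPM in follicular B-like cells. Il2rg stood at 432 CPM in follicular B-like, 167 CPM in cluster 11 and 90.0 CPM in plasma cell-like cells.

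**Figure D1:**
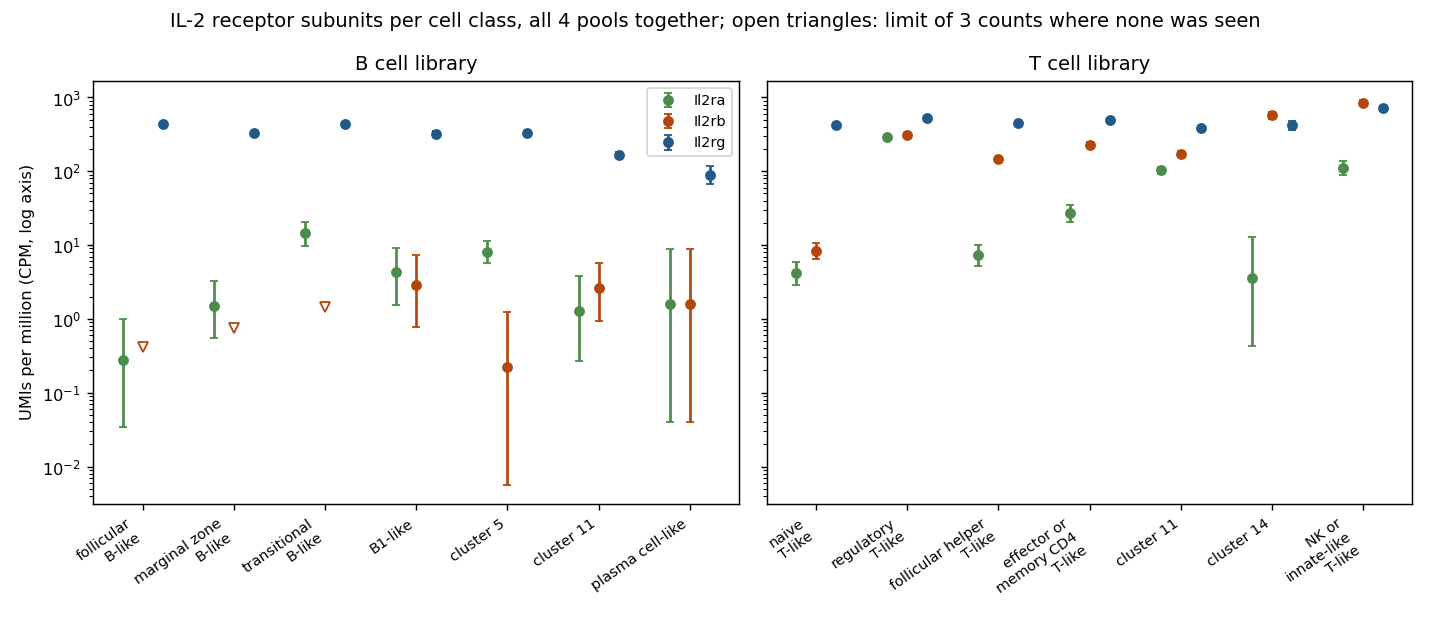
Levels of Il2ra, Il2rb and Il2rg (CPM, log axis) in cell classes of the B and T libraries, each point the sum over the cells of a class in all 4 pools with its 95% Poisson interval, and open triangles the 3-count limit where no UMI was counted. Il2rb stood at 846 CPM in NK or innate-like T cells and under 0.420 CPM in follicular B-like cells, while Il2rg stood at 709 and 432 CPM.

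Follicular B-like cells made up a smaller share of the B library at day 4 in both genotypes, and cluster 11, which carried germinal center and cycling markers, a larger share in controls. Follicular B-like cells were 39.6% (36.7 to 42.5%) of control and 35.9% (33.0 to 39.0%) of KO cells at day 0, and 20.2% (18.1 to 22.4%) and 18.1% (16.4 to 19.8%) at day 4. The day 4 over day 0 ratios were 0.509 (0.437 to 0.593) in control and 0.503 (0.433 to 0.584) in KO. Transitional B-like cells were also a smaller share at day 4, with ratios of 0.379 (0.275 to 0.518) in control and 0.433 (0.325 to 0.574) in KO. These are shares of all cells of a pool, and clusters without a name may hold cells of the same types in another state. A smaller share is therefore not shown to be a loss of follicular or transitional B cells. Cluster 1, without a name, made up 1.60, 1.37, 30.6 and 33.0% (18, 14, 426 and 639 cells) of control day 0, KO day 0, control day 4 and KO day 4. It had day 4 over day 0 ratios of 19.1 (11.96 to 32.6) in control and 24.0 (14.2 to 44.1) in KO. Cluster 11 held 4, 15, 33 and 40 cells in control day 0, KO day 0, control day 4 and KO day 4, or 0.355, 1.47, 2.37 and 2.06%. Its KO over control ratio was 4.14 (1.32 to 17.2) at day 0 and 0.871 (0.536 to 1.43) at day 4, and its day 4 over day 0 ratio was 6.67 (2.37 to 25.9) in control and 1.40 (0.757 to 2.73) in KO. Plasma cell-like cells numbered 6, 6, 12 and 4, with a KO over control ratio of 1.11 (0.295 to 4.13) at day 0 and 0.240 (0.0563 to 0.790) at day 4. Marginal zone B-like cells had KO over control ratios of 1.19 (0.864 to 1.64) and 1.01, and B1-like cells 0.842 and 0.872, all with intervals that included 1. Cells of other lineages, among them dendritic, monocyte and erythroid types, were 2.22, 2.94, 5.31 and 3.30% of the B library.

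Follicular helper T-like cells, the CD4 T cells that help germinal centers, were a larger share of the T library at day 4 in both genotypes. The extract protocol names a naive CD4+ T cell kit, so T shares describe cells that passed that isolation. Follicular helper T-like cells numbered 7, 29, 217 and 252, or 0.697, 2.19, 10.6 and 7.74%, with day 4 over day 0 ratios of 15.2 (7.26 to 38.3) in control and 3.53 (2.40 to 5.39) in KO. Their KO over control ratio was 3.14 (1.35 to 8.498) at day 0 and 0.730 (0.606 to 0.879) at day 4. Regulatory T-like cells were 7.66, 8.76, 12.9 and 12.8%, 1.68-fold (1.30 to 2.20) higher at day 4 in control and 1.46-fold (1.18 to 1.81) in KO. Effector or memory CD4 T-like cells had a KO over control ratio of 1.14 at day 0 and 0.700 (0.554 to 0.885) at day 4. At day 4 the KO over control ratio was 1.57 (1.36 to 1.81) for naive T-like cells, with values under other settings given below. For the unnamed cluster 5 it was 0.483 (0.381 to 0.611). Shares of 1 pool add up to the whole, so they do not vary independently. NK or innate-like T cells were lower in KO at day 0, 0.379 (0.185 to 0.745), and 1.14 (0.699 to 1.90) at day 4. The cycling cluster 11 of the T library was 7.12-fold (2.63 to 27.0) higher at day 4 in control and 2.41-fold (1.33 to 4.73) in KO. The naive T-like share was 21.1, 17.5, 13.5 and 21.1%, and its day 4 over day 0 ratio in KO, 1.20, lay below 1 under 4 other settings. In control the ratio was 0.639, and between 0.293 and 0.964 under other settings. This class does not hold all cells with naive markers. Cluster 1 of the T library, with the naive markers Igfbp4 and Dapl1 among its top genes, held 19.4, 22.6, 20.5 and 22.7%. Cluster 3, left unnamed though its naive T list stood at 0.55, held 20.2, 18.1, 10.45 and 12.2%. The naive T-like ratios are therefore not those of all naive cells.

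**Figure D2:**
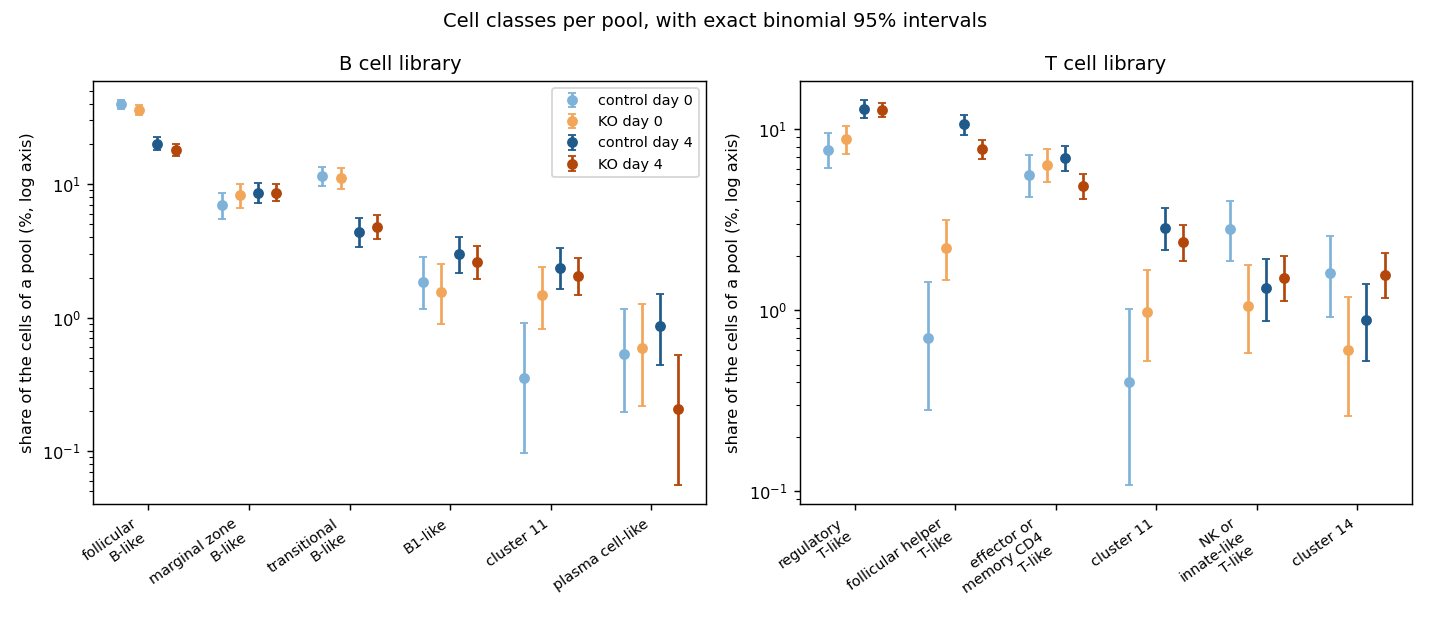
Share of the cells of a pool (percent, log axis) in cell classes of the B and T libraries, each point 1 pool with its exact 95% binomial interval. Follicular helper T-like cells were 0.697, 2.19, 10.6 and 7.74% of control day 0, KO day 0, control day 4 and KO day 4 cells.

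Over all B-library cells, genes of the secretory pathway and of ribosome biogenesis were higher at day 4 than at day 0 in both genotypes, and most chemokine receptors and trafficking genes were lower. Of the secretory pathway and unfolded protein response list, 19 of 19 members were higher in control (median log2 ratio 0.33, percentile 100) and 17 of 19 in KO (0.28, percentile 100). Within classes the control medians were −0.07 (8 of 19) in follicular, −0.14 (7 of 19) in marginal zone and 0.05 (11 of 18) in transitional B-like cells, all inside the random range. The KO medians were 0.06 (13 of 19), 0.13 (11 of 19) and 0.28 (12 of 19), and only the last lay outside it. No median was taken within cluster 1, which held 30.6% of control and 33.0% of KO cells at day 4. Medians within the other classes therefore cannot tell a change of mix from a change of state. Manf, an endoplasmic reticulum stress protein, stood at 258 against 150.3 CPM in control, 1.72-fold (1.59 to 1.85), and Sdf2l1 at 105 against 62.3 CPM, 1.69-fold. Hsp90b1, an endoplasmic reticulum chaperone, stood in KO at 672 against 340 CPM, 1.98-fold (1.88 to 2.07). MYC and ribosome biogenesis genes were higher for 16 of 18 members in control (0.23, percentile 99.99) and 18 of 18 in KO (0.34, percentile 100). Within the same classes they stood at 0.10, 0.15 and 0.05 in control and 0.14, 0.04 and 0.07 in KO. Srm, a polyamine synthesis enzyme, was 1.72-fold (1.52 to 1.94) higher in control and 1.55-fold in KO, and Nop58, a nucleolar protein, stood in KO at 124 against 84.4 CPM. Glycolysis genes had medians of 0.24 (11 of 15 higher, percentile 99.99) in control and 0.08 (10 of 15) in KO. By class, in the same order, the glycolysis medians were 0.01, 0.22 and −0.02 in control and 0.11, −0.01 and 0.23 in KO. Hk2, a hexokinase, stood in control at 16.7 against 8.76 CPM, 1.91-fold (1.41 to 2.62), and Gapdh was 1.56-fold higher in control and 1.23-fold in KO.

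Chemokine receptors and trafficking genes were lower at day 4 over all cells, with medians of −0.35 (4 of 15 higher, percentile 0.02) in control and −0.19 (5 of 15, percentile 0.03) in KO. Within follicular, marginal zone and transitional B-like cells the medians were −0.14, −0.02 and −0.08 in control and −0.04, 0.06 (8 of 14 higher) and −0.08 in KO, all inside the random range. Cluster 1 was again not covered by these medians. Ccr7, the receptor that guides lymphocytes to T cell zones, stood at 71.5 against 143 CPM in control, 0.502 (0.456 to 0.552), and at 81.1 against 139 CPM in KO, 0.583 (0.533 to 0.638). Klf2, a quiescence factor, was 0.672 of its day 0 level in control. Cxcr3 and Gpr183 were higher in both genotypes, Cxcr3 3.60-fold (2.08 to 6.68) and 3.19-fold, Gpr183 1.27-fold and 1.69-fold. Antigen presentation and costimulation genes had medians of 0.11 (12 of 17 higher) and 0.09 (11 of 17). Cd83, an activation marker, stood at 340 against 138 CPM in control, 2.46-fold (2.29 to 2.65), and at 409 against 136 CPM in KO, 3.01-fold (2.80 to 3.24). Among STAT5-responsive genes (0.05, 7 of 13 higher, and −0.13, 4 of 13), the feedback inhibitors Socs1 and Socs3 were higher, Socs1 3.32-fold (2.60 to 4.30) in control and 3.26-fold in KO, Socs3 4.26-fold and 2.86-fold. Socs1 and Cd83 were among the top genes of cluster 1, so their values over all cells also depend on its share. That share went from 1.60 to 30.6% in control and from 1.37 to 33.0% in KO. In the IL-2 family list (−0.12, 6 of 15, and −0.04, 7 of 15), Il2rg was 0.751 of its day 0 level in control and 0.973 (0.926 to 1.02) in KO, and Il2ra 0.690 (0.368 to 1.31) and 0.920 (0.475 to 1.87), while Jak3 was 1.67-fold and 1.41-fold higher.

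The BCL2 family (0.13, 7 of 13 higher, and 0.00, 7 of 13, with the control median 0.00 in lineage cells alone) split, with Bcl2a1d 1.99-fold (1.68 to 2.37) and 1.53-fold higher, and the pro-apoptotic Bmf at 0.412 and 0.334. Somatic mutation and switch repair genes had medians of −0.02 (8 of 17) and 0.08 (10 of 17), with Ung, a uracil glycosylase, 1.76-fold (1.30 to 2.41) higher in control. Amino acid transport and mTORC1 genes had medians of −0.13 and −0.12, with 3 of 13 members higher in each genotype and the stress-responsive Sesn1 at 0.710 and 0.751. Immediate early genes had medians of −0.19 and −0.18 (5 of 16 higher in each), and −0.31 and −0.05 with B lineage cells alone. Within follicular B-like cells they stood at −0.04 and 0.26 (10 of 13). Type I interferon genes were higher in control (0.23, 13 of 14, percentile 99.99) and not in KO (−0.15, 5 of 14), and with B lineage cells alone the control median was 0.05 (7 of 14). The interferon medians within follicular, marginal zone and transitional B-like cells were 0.31, 0.50 and 0.23 in control and −0.00, 0.42 and 0.03 in KO. Immunoglobulin heavy chain constant genes had a median of 0.91 in control (4 of 7 higher, percentile 100), with Igha at 371 against 8.29 CPM and Ighg3 at 127 against 4.38 CPM. Of the control day 4 UMIs of Ighg3, 56.4% lay in 1 cell, and the share for Igha, given below, was nearly as large. The median was −0.09 in KO, where Ighg1 stood at 65.9 against 1.99 CPM with 86.7% of its UMIs in 1 cell.

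By size alone, the highest genes of the B library at day 4 in control were S100a8, Camp, Ltf, Mpo, S100a9 and Lcn2, genes of myeloid cells, with S100a8 at 1061 against 0.313 CPM. Ccl5 (0.355, but higher with B lineage cells alone, with a log2 ratio of 1.07 from 16 against 4 UMIs), Abca1 (0.382), Bmf (0.412) and Tsc22d3 (0.455) were among the lowest. With B lineage cells alone and no gene led by 1 cell, a rule added after these values were seen, the highest were Gm26740 (58.0-fold), Nfil3 (26.2-fold, 8.77 to 129), Pclaf (14.5-fold, 10.9 to 19.7), Lifr (14.2-fold), Birc5 (12.5-fold) and Mef2b (11.98-fold) in control. Pclaf and Birc5 act in dividing cells and Mef2b in germinal center B cells. In KO the highest included Nfil3 (11.4-fold), Lifr (10.9-fold), Samsn1 (558 against 98.5 CPM, 5.67-fold, 5.20 to 6.18), Gadd45g (3.61-fold) and Cd83 (3.12-fold). Lifr, Samsn1, Gadd45g and Cd83 were among the top genes of cluster 1 of the B library. The lowest were Myadm (0.385), Sgk1 (0.393), Ahnak (0.394) and the glucocorticoid-induced Tsc22d3 (0.442, 0.405 to 0.481) in control, and Rgs2 (0.347), Myb (0.389) and Tifa (0.469) in KO. Across genes, which are not independent replicates, the day 4 over day 0 log2 ratios of control and KO had a Pearson correlation of 0.453.

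Between genotypes, B-library cells at day 0 had higher type I interferon genes and lower secretory pathway genes in KO than in control. Of the interferon list 13 of 14 members were higher in KO (median 0.43, percentile 100), led by Zbp1, a nucleic acid sensor, at 52.7 against 30.8 CPM, 1.71-fold (1.43 to 2.05), Oasl2 at 1.62-fold (1.22 to 2.16) and Ifi27l2a at 1107 against 694 CPM, 1.59-fold (1.53 to 1.66). Isg20 was the other way, at 0.786. Cluster 8, led by interferon-induced genes, was a larger share of KO than of control B-library cells, with ratios of 1.89 (1.25 to 2.90) at day 0 and 1.71 (1.20 to 2.496) at day 4. Of the secretory list 3 of 19 members were higher in KO (−0.26, percentile 0), with Creld2 at 33.7 against 67.9 CPM, 0.496 (0.417 to 0.587), Hsp90b1 at 340 against 572 CPM, 0.595 (0.563 to 0.628), and Sdf2l1 at 0.719. Within follicular, marginal zone and transitional B-like cells the secretory medians were −0.07, −0.14 and −0.10, all inside the random range. MYC and ribosome biogenesis genes were lower over all assigned cells (−0.20, 1 of 18 higher, percentile 0; Myc 66.2 against 86.7 CPM), but not with B lineage cells alone (0.02, 11 of 18). Antigen presentation genes were higher over all cells (0.10, 12 of 16; Cd86 1.36-fold) and at −0.00 in lineage cells alone. Glycolysis genes were higher for 11 of 15 members (0.08, percentile 99.6), with Pgam1 at 104 against 85.1 CPM, and within follicular, marginal zone and transitional B-like cells the medians were −0.05, 0.15 and 0.04.

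At day 4 the secretory list was again lower in KO B-library cells, with 0 of 19 members higher (−0.33, percentile 0). The day 4 medians within follicular, marginal zone and transitional B-like cells were 0.05 (11 of 19), 0.03 (10 of 19) and 0.09 (11 of 19), all inside the random range, and plasma cell-like cells numbered 4 in KO against 12 in control. Creld2 stood at 55.1 against 101 CPM, 0.546 (0.498 to 0.597), Manf at 179 against 258 CPM, 0.695 (0.659 to 0.733), and Dnajb9 at 0.727. Immunoglobulin constant genes had a median of −0.28 (1 of 7 higher, percentile 0.01) at day 4 and 0.11 (4 of 7) at day 0. Igha stood at 11.7 against 371 CPM at day 4, 0.0314 (0.0267 to 0.0366), with 49.98% of the control UMIs in 1 cell, and Ighg2c and Ighg3 had 50.9 and 56.4% of theirs in 1 cell. Ighm was 0.822 of the control level. Glycolysis genes were lower (−0.13, 3 of 15 higher, percentile 0.02; Pgam1 0.827; −0.06, 7 of 15, in lineage cells alone), as were MYC genes (−0.07, 4 of 18; Srm 0.775, 0.712 to 0.844). By class, in the same order, these medians were 0.06, −0.12 and 0.17 for glycolysis and 0.06, −0.07 and −0.10 for MYC genes. Trafficking genes were higher in KO over all cells (0.17, 9 of 15, percentile 99.91). In lineage cells alone the median was 0.10 (10 of 15), and within these classes 0.04, −0.07 and −0.02, all inside the random range. Ccr6 stood at 108 against 82.0 CPM, 1.32-fold (1.21 to 1.43), and Cxcr5, the follicle homing receptor, at 108 against 86.2 CPM, 1.26-fold (1.16 to 1.36), while the integrin Itgb1 was 0.682. The day 0 trafficking median was −0.04 (6 of 15), and −0.12 (3 of 15, percentile 0.545) in lineage cells alone.

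Antigen presentation genes were also higher in KO at day 4 over all cells (0.13, 14 of 17, percentile 98.9). In lineage cells alone the median was 0.07 (14 of 17), inside the random range. It was −0.01, −0.12 (2 of 13, percentile 0.105) and 0.13 within follicular, marginal zone and transitional B-like cells. The costimulatory ligand Icosl stood at 91.4 against 72.1 CPM, 1.27-fold (1.16 to 1.38), and Cd86 at 1.23-fold. Immediate early genes had medians of 0.14 (10 of 16 higher; Egr2 2.04-fold, Cd69 1.36-fold) at day 4 and 0.02 (9 of 15; Fos 0.514) at day 0. In the IL-2 family list (0.11, 10 of 15, at day 4, and 0.01, 8 of 15, at day 0; 0.06 and −0.05 in lineage cells alone), Il2rg was 1.18-fold (1.13 to 1.23) higher in KO at day 4 and 0.908 (0.858 to 0.961) at day 0, and Il2ra 0.9901 (0.566 to 1.75) and 0.742 (0.347 to 1.54). STAT5-responsive genes had medians of 0.03 (7 of 14; −0.14 in follicular and 0.30 in marginal zone B-like cells) and, at day 0, 0.08 (11 of 13, percentile 97.7; 0.04, inside the random range, in lineage cells alone; Id2 2.24-fold). The BCL2 family stood at −0.04 (5 of 13; Bcl2 1.14-fold) and 0.03 (7 of 13; −0.06 in lineage cells alone; Bbc3 1.97-fold). Amino acid genes stood at −0.04 (5 of 13) and 0.03 (7 of 13), with the transporter Slc7a5 lower in KO on both days, 0.688 and 0.625. Repair genes stood at 0.04 (9 of 17; Apex2 1.79-fold) and −0.16 (7 of 17; 0.00 in lineage cells alone; Hmces 1.47-fold). Interferon genes at day 4 had a median of 0.03 (7 of 14), and 0.22 (12 of 14, percentile 100) in lineage cells alone, with Ifi27l2a 1.45-fold (1.42 to 1.49) higher and Isg15 at 0.722.

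Named by size alone, the genes that differed most between genotypes in the B library lay in few cells. At day 0 Mpo, a myeloid granule enzyme, was counted 263 times in KO and 0 times in control with 99.6% of UMIs in 1 cell, Ighg2b was 0.0429 of control with 95.8% of control UMIs in 1 cell, and Ermap, an erythroid gene, was 0.0877. At day 4 Hbb-bs stood at 419 against 1.12 CPM with 99.6% of UMIs in 1 cell, and Ltf at 0.0689 against 66.8 CPM. With B lineage cells alone and no gene led by 1 cell, the lowest in KO at day 0 included Gm43305 (0.410), Glt8d1 (0.518), Slc15a2 (0.541) and Hsp90b1 (0.566), and the highest Gm26740 (73.7-fold, 46.5 to 125), Psd3 (3.08-fold), Lgals3bp (2.30-fold, 1.64 to 3.25) and Cks2 (1.79-fold). At day 4 the lowest were Jchain, the joining chain of secreted antibody (518 against 1662 CPM, 0.312, 0.303 to 0.321), Gm43305 (0.407), Eaf2 (0.416) and Tent5c (0.516), and the highest Psd3 (3.14-fold), Rell1 (2.02-fold) and Asb2 (1.96-fold). Jchain and Tent5c were among the top genes of the plasma cell-like cluster, and Eaf2 was on the plasma cell marker list. That class held 4 KO and 12 control cells at day 4, so these 3 values also depend on its share. Across genes the KO over control log2 ratios of day 0 and day 4 had a Pearson correlation of −0.0409.

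**Figure D3:**
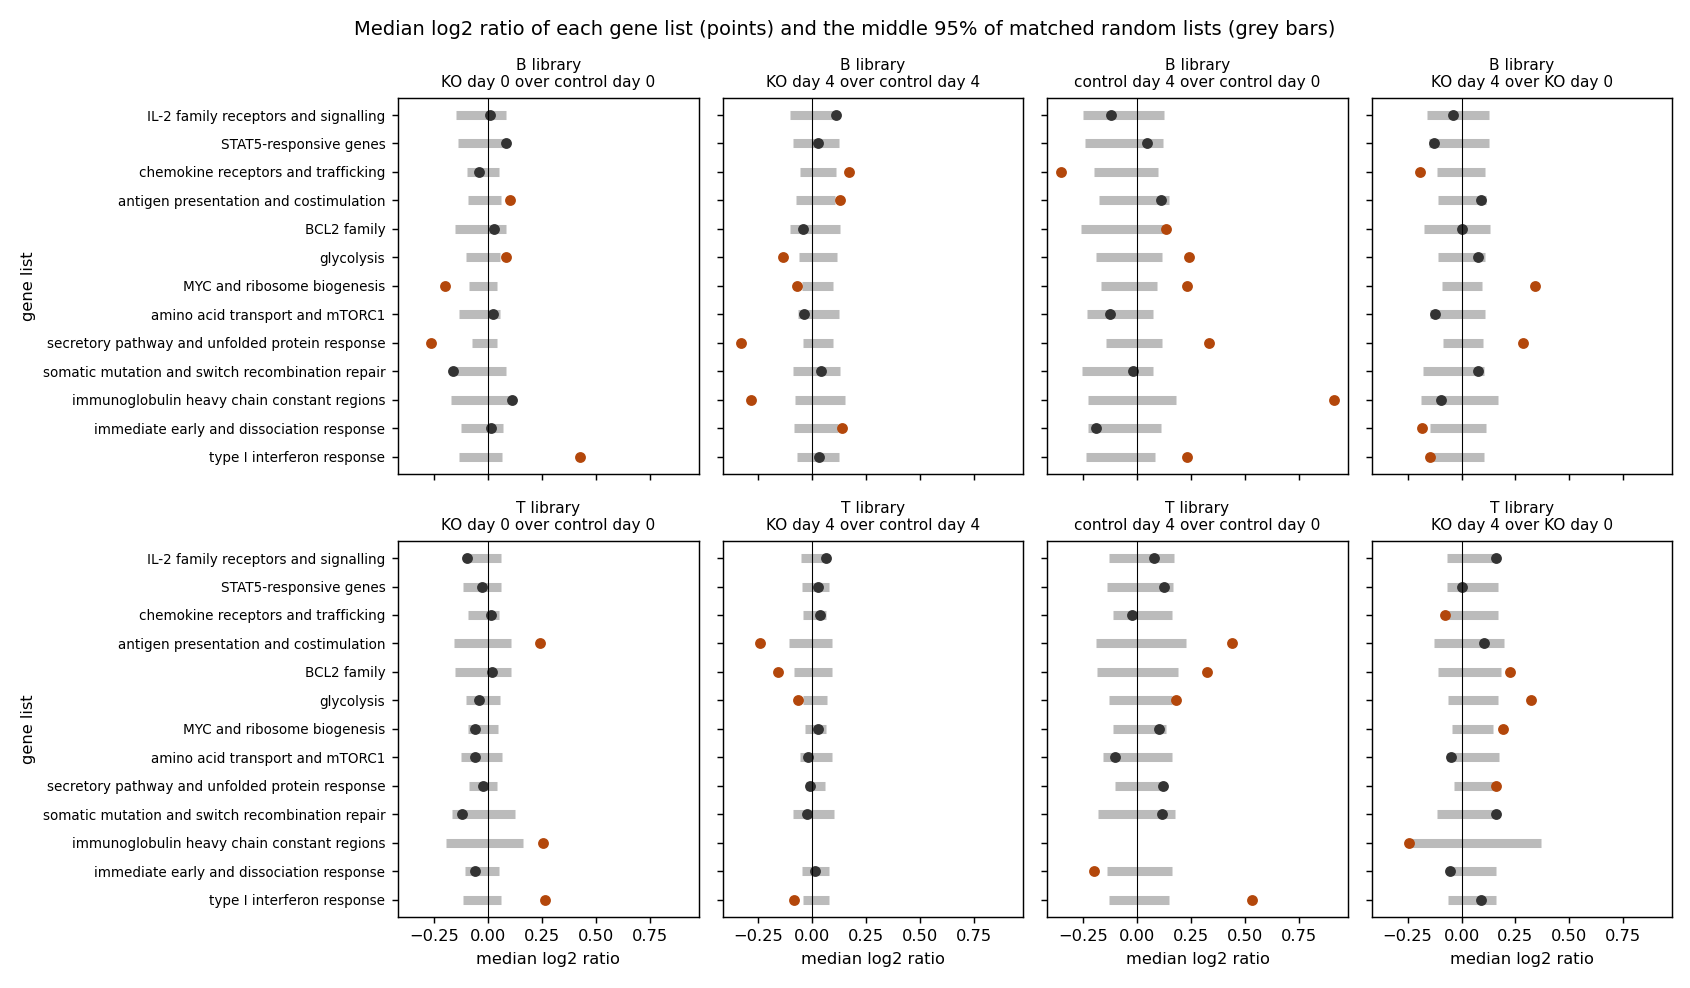
Median log2 ratio of each gene list in the 4 comparisons of each library, all assigned cells, as points, with the middle 95% of matched random lists as grey bars and medians outside it in orange. Secretory pathway genes stood at −0.26 and −0.33 in KO over control B-library cells at day 0 and day 4, and at 0.33 and 0.28 in day 4 over day 0 cells of control and KO.

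Over all T-library cells, interferon and antigen presentation genes were higher at day 4 than at day 0 in control, and BCL2 family and glycolysis genes were higher in both genotypes. Within naive T-like cells antigen presentation and glycolysis genes were not higher. The interferon list had a median of 0.53 in control (12 of 14 higher, percentile 100), with Isg20 at 667 against 95 UMIs, 2.497-fold (2.01 to 3.13), and Isg15, a ubiquitin-like interferon product, at 115 against 54.1 CPM, 2.13-fold (1.86 to 2.44). In KO the interferon median was 0.09 (10 of 14), with Isg15 1.33-fold higher and Ifi27l2a 1.83-fold. Antigen presentation and costimulation genes had medians of 0.44 (12 of 16, percentile 99.96; 0.71 in lineage cells alone) and 0.11 (9 of 16), and H2-DMa stood at 89.7 against 36.2 CPM in control, 2.48-fold (2.11 to 2.92), and at 104 against 32.1 CPM in KO, 3.24-fold (2.81 to 3.76). BCL2 family genes had medians of 0.33 (11 of 13, percentile 99.91) and 0.22 (10 of 14, percentile 99.3), led by the survival genes Bcl2a1b, 2.495-fold and 2.18-fold, and Bcl2a1d, 2.34-fold and 2.22-fold. Glycolysis genes had medians of 0.18 (12 of 15, percentile 98.9) and 0.32 (13 of 15, percentile 100), with Gapdh 1.63-fold and 1.40-fold higher. Within naive T-like cells, in control and KO, the medians were −0.04 (1 of 6) and −0.30 (2 of 7, percentile 0.92) for antigen presentation, −0.11 (6 of 14) and 0.04 (8 of 14) for glycolysis, 0.24 and 0.30 for the BCL2 family and 0.35 and −0.06 for interferon genes. Regulatory T-like cells joined clusters 4 and 9, and 13 of 77, 21 of 116, 116 of 264 and 121 of 416 of them were of cluster 9 in control day 0, KO day 0, control day 4 and KO day 4, so medians within this class also depend on that mix. Its medians were 0.30 and 0.08, 0.15 and 0.22, 0.15 and 0.04, and 0.59 and 0.43 in the same order, and within effector or memory CD4 T-like cells 0.16 and −0.13, −0.18 and −0.06, 0.13 and 0.15, and 0.24 and −0.07.

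MYC genes had medians of 0.10 (12 of 18) in control and 0.19 (17 of 18, percentile 99.89) in KO, where Myc stood at 62.9 against 42.4 CPM, with a ratio interval of 1.30 to 1.70. Secretory genes were higher for 16 of 19 members in each genotype (0.12 and 0.16), with the signal peptidase subunit Sec11c 1.67-fold and 1.52-fold. Within naive T-like cells the medians were 0.15 and 0.25 for MYC genes and −0.10 (9 of 19) and 0.09 (14 of 19) for secretory genes, and within regulatory T-like cells −0.05 and −0.12, and 0.15 and 0.01. Repair genes had medians of 0.12 and 0.16 (12 of 17 higher in each). In the IL-2 family list (0.08, 8 of 15, and 0.16, 11 of 15), Il7r, a receptor of naive and memory T cells, was lower at 0.550 (0.522 to 0.580) and 0.675, and Il4ra higher at 1.52-fold and 2.03-fold (1.83 to 2.25). Il2ra was 1.38-fold (1.16 to 1.65) higher in control. Socs1 was 1.64-fold and 1.59-fold higher within STAT5 lists of 0.13 (9 of 14) and 0.00 (7 of 14). Within naive T-like cells the STAT5 medians were 0.34 (7 of 12, percentile 99.99) and 0.35 (8 of 12, percentile 100), and within regulatory T-like cells 0.08 in each genotype. Trafficking genes had medians of −0.02 (7 of 15) and −0.08 (5 of 15), with Cxcr5 at 3.83-fold (2.44 to 6.31) and 2.08-fold, and Ccr7 at 0.663 in control. Immediate early genes stood at −0.20 (3 of 15, percentile 0.38; Jun 0.493, 0.442 to 0.550) and −0.05 (6 of 15), and amino acid genes at −0.10 and −0.05 (6 of 13 higher in each; Sesn1 0.573 in control).

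The largest T-library differences by size alone were again of other lineages, with Hbb-bs, a hemoglobin chain, at 426 against 3.16 CPM in control and 3.91 against 1120.0 CPM in KO. With T lineage cells alone and no gene led by 1 cell, the highest in control were Gm26740 (20.2-fold) and genes of cell division, among them Tk1 (19.6-fold), Cdk1 (16.7-fold), Cenpf (16.3-fold), Ube2c (13.6-fold), Ccna2 (10.6-fold) and Pclaf (10.2-fold). In KO they included Il21, the cytokine of follicular helper T cells (9.09 against 1.13 CPM, 8.05-fold, 3.83 to 20.3), Il4 (21.8 against 3.71 CPM, 5.89-fold, 3.87 to 9.38), the inhibitory receptors Lag3 (4.24-fold) and Tigit (4.20-fold, 3.22 to 5.57), and Anxa2 (4.83-fold). Slc15a2 (0.0181), Klrd1 (0.432) and Jun (0.464) were among the lowest in control, and Dapk1 (0.358) and Ly6c1 (0.459) in KO.

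Between genotypes, T-library cells at day 0 had higher interferon genes in KO than in control, and at day 4 the median over all cells was the other way. Of the interferon list 13 of 14 members were higher in KO at day 0 (0.26, percentile 100), with Oasl2 2.10-fold (1.33 to 3.42), Usp18 1.55-fold and Rtp4 1.47-fold (1.26 to 1.73). The interferon-led cluster 8 of the T library had a KO over control share ratio of 1.40 (0.943 to 2.12) at day 0 and 1.06 (0.8025 to 1.41) at day 4. At day 4 the list stood at −0.08 (6 of 14, percentile 0.04), with Oasl2 at 0.663, Ifit3 at 0.675 and Isg20 at 0.710. Within naive, regulatory and effector or memory T-like cells the interferon medians were 0.59, 0.30 and 0.06 at day 0, and 0.05 (7 of 14), 0.07 (9 of 14) and −0.09 (5 of 14), all inside the random range, at day 4. Antigen presentation genes were higher in KO at day 0 (0.24, 12 of 14, percentile 99.97), where Cd74 and H2-Aa, class II genes of antigen presenting cells, stood at 64.0 against 19.6 CPM and 10.7 against 4.42 CPM. At day 4 they were lower (−0.24, 3 of 16, percentile 0.01), with H2-Aa at 0.504 (0.362 to 0.699) and H2-DMa at 1.16-fold. Within naive, regulatory and effector or memory T-like cells the day 4 medians were 0.17 (5 of 7), −0.20 (3 of 10) and −0.09 (3 of 10). The share of cells of other lineages in the T library was 2.59, 3.17, 2.69 and 0.737%.

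BCL2 family genes stood at 0.02 (7 of 12) at day 0 and −0.16 (5 of 14, percentile 0.09) at day 4, the latter at −0.07 in lineage cells alone, with Bcl2a1d at 0.769 and Bcl2 1.13-fold (1.08 to 1.19). Glycolysis genes stood at −0.04 (5 of 15; Pkm 0.827) and −0.07 (5 of 15; −0.03 in lineage cells alone; Gapdh 0.927), MYC genes at −0.06 (6 of 18; Myc 0.796) and 0.03 (12 of 18). In the IL-2 family list (−0.10, 4 of 15, and 0.07, 10 of 16), Il4ra was 0.864 and 1.15-fold, Il7r 0.942 and 1.16-fold, Il2rg 0.921 and 1.04-fold, and Il2ra 1.12 (0.911 to 1.37) and 0.998 (0.901 to 1.11). STAT5 genes stood at −0.03 (7 of 14; Id2 0.740) and 0.03 (10 of 14; Cish 1.23-fold), and trafficking genes at 0.02 and 0.03 (9 of 15 in each), with Ccr7 1.19-fold and Cxcr5 at 0.764 (0.638 to 0.917) at day 4. Secretory genes stood at −0.02 (7 of 19) and −0.01 (8 of 19), amino acid genes at −0.06 (4 of 13) and −0.02 (6 of 13), repair genes at −0.12 (5 of 16) and −0.02 (7 of 17), and immediate early genes at −0.06 (6 of 15; Jun 0.705) and 0.01 (9 of 15). Immunoglobulin constant genes stood at 0.26 (3 of 3) at day 0.

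Named by size alone, the hemoglobin genes were far apart between genotypes in the T library on both days, with Hbb-bs at 1120.0 against 3.16 CPM at day 0 and 3.91 against 426 CPM at day 4, and 64.9 and 82.4% of the higher pool's UMIs in 1 cell. With T lineage cells alone and no gene led by 1 cell, the lowest in KO at day 0 included Klrd1 (0.531), Ccl5 (0.566, 0.514 to 0.622) and Cxcr6 (0.576), genes of cytotoxic and innate-like T cells, and the highest Gm26740 (22.6-fold), Apobec1 (2.21-fold) and Trp53inp1 (1.86-fold). Cxcr6 was among the top genes of NK or innate-like T cells and Klrd1 of cluster 14. Each class had a KO over control share ratio of 0.379 at day 0, so these values also depend on those shares. At day 4 Rsad2 (0.312, 0.241 to 0.402), Gm43305 (0.331) and Nr4a2 (0.539) were among the lowest in KO, and Adamts13 (7.32-fold), Rell1 (2.55-fold) and Ly6c2 (2.22-fold, 1.94 to 2.56) among the highest.

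Some genes differed between pools in B and T cells alike, and were chosen after their values were seen. Gm26740 stood in B lineage cells at 3.09 CPM in control day 0, 228 in KO day 0, 179 in control day 4 and 192 CPM in KO day 4, and in T lineage cells at 5.93, 134, 119.6 and 127 CPM. Slc15a2, a peptide transporter, was counted at day 0 in both genotypes, at 14.6 and 7.89 CPM in B and 21.5 and 12.4 CPM in T cells, and at day 4 at 0.492 and 0.442 CPM in B, 0.390 CPM in control T and 0 UMIs in KO T cells. Psd3 was higher in KO on both days in both libraries, at 27.5 against 8.93 CPM and 14.2 against 4.53 CPM in B cells, and Gm43305 lower, at 88.1 against 215 CPM and 120.3 against 295 CPM. Adamts13 was higher in KO than in control at day 4 alone, at 4.78 against 0.492 CPM in B and 6.28 against 0.857 CPM in T cells.

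**Figure D4:**
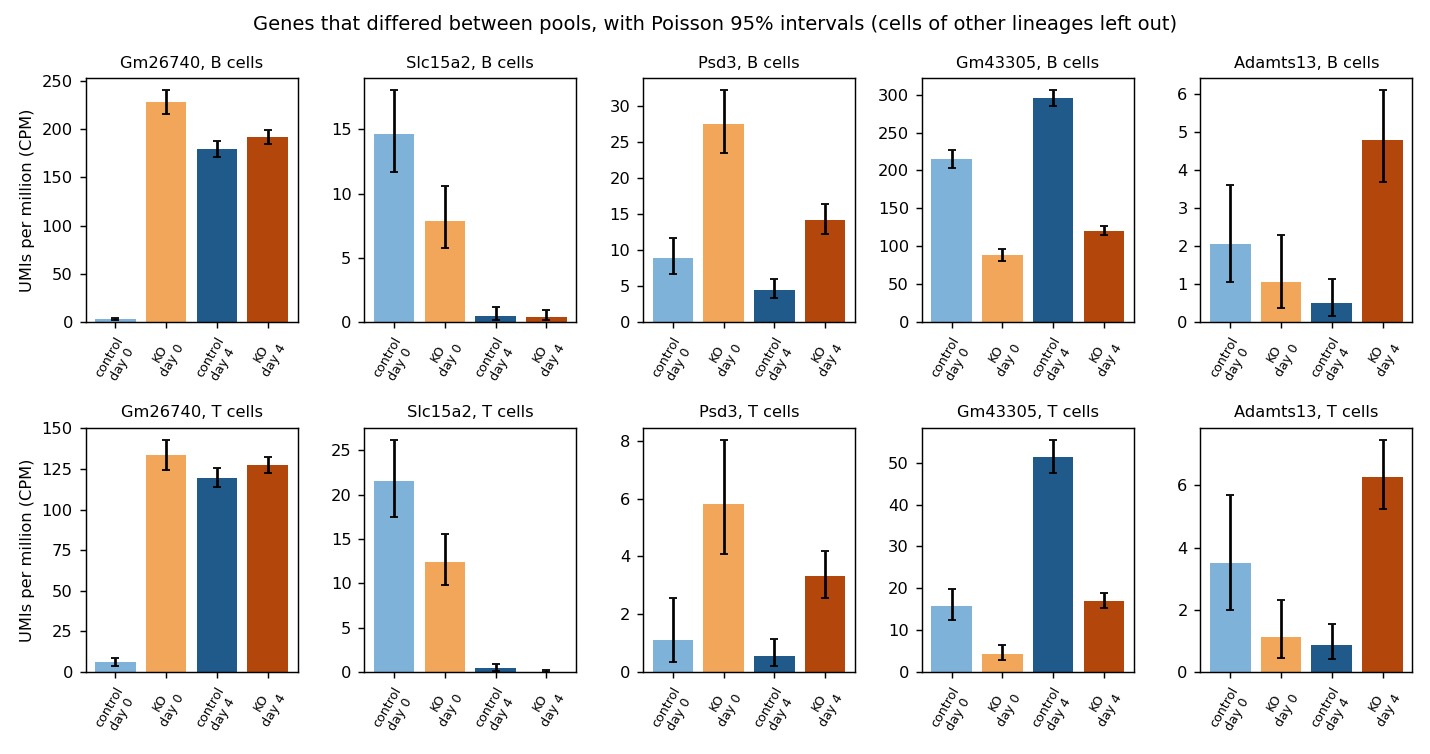
Levels (CPM) of 5 genes in B and T lineage cells of the 4 pools, each bar 1 pool with its 95% Poisson interval and its own scale per panel. Gm26740 stood in T cells at 5.93 CPM in control day 0 and at 134, 119.6 and 127 CPM in KO day 0, control day 4 and KO day 4.

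Cell classes within each library were compared by the same lists. Against follicular B-like cells, cluster 11 of the B library (92 cells) had higher secretory genes (median 1.83, 19 of 19), glycolysis genes (1.38, 12 of 15; Hk2 5.05-fold), repair genes (0.91, 13 of 17; Exo1 28.2-fold, Ung 9.35-fold) and immunoglobulin constant genes (5.98, 6 of 7). Its trafficking genes were lower (−1.65, 4 of 15; Ccr7 0.0960), as was the IL-2 family list (−1.11, 0 of 11; Il4ra 0.288, Jak1 0.380). Plasma cell-like cells had secretory genes at 2.79 (19 of 19; Creld2 1028 against 24.2 CPM) and antigen presentation genes at −3.79. Cluster 5 had MYC genes at 1.94 (18 of 18; Srm 8.39-fold, Myc 5.23-fold), and transitional B-like cells had interferon genes at 0.88 (13 of 14) and immediate early genes at 0.50. Marginal zone B-like cells had Klf2 at 146 against 1065 CPM, 0.138, and B1-like cells had Cxcr3 at 46.8 against 0.420 CPM and BCL2 family genes at 0.48 (11 of 12).

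Against naive T-like cells, regulatory T-like cells had antigen presentation and costimulation genes at 1.95 (10 of 12; Tnfrsf4 313 against 10.9 CPM), IL-2 family genes at 0.28 (11 of 14; Il2ra 71.0-fold, Il2rb 37.7-fold) and STAT5 genes at 0.33 (Cish 7.36-fold). Follicular helper T-like cells had interferon genes at 0.98 (13 of 14; Ifi27l2a 5.90-fold), STAT5 genes at −0.32 (4 of 13; Bcl2 0.225), Cxcr5 at 59.7 against 0.390 CPM and Il7r at 0.214. Effector or memory CD4 T-like cells had Id2, an inhibitor of E proteins, at 539 against 52.7 CPM, and NK or innate-like T cells had STAT5 genes at 0.78 and Il2rb 102-fold (78.4 to 134) higher. Over all lineage cells, B against T, antigen presentation genes stood at 3.69 (13 of 18), secretory genes at 0.52 (15 of 19), MYC genes at 0.38 (17 of 18), the IL-2 family at −0.57 (4 of 16; Il7r 0.935 against 346 CPM, Il9r 9.14-fold), STAT5 genes at −1.15 (3 of 14) and interferon genes at −0.78 (1 of 14). These 2 libraries were prepared in parallel from the same spleens, so libraries were compared here, not replicated cell types.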

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

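The tests of the cluster 1 cells, of distance to the edited locus and of the secretory list without plasma cell-like and cluster 11 cells were chosen only after the result was seen. Most results below were picked out because a KO over control value, or a day 4 over day 0 value, lay on opposite sides of no difference in the 2 groups compared. The share of cluster 11 B cells, the genes that differed in B and T cells alike and the secretory list did not meet this rule. Each group was 1 pool, and none of these differences between groups was tested.

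The follicular helper T-like share was higher in KO at day 0, with a ratio of 3.14, and lower at day 4, 0.730, and the difference was not tested, while cluster 11 B cells were also more frequent in the KO day 0 pool, 15 cells against 4 in control. One explanation is that day 4 cells carried the KO day 0 hashtag. The 14 cluster 1 cells of that pool, a state found mainly at day 4, would bring 0.960 cluster 11 cells, against 15 seen (8.40 to 24.7), which argues against it for the B cells. For the T cells it stays open. Gm16867, counted almost only in the KO day 0 pool, stood at 2.21 CPM (0.0559 to 12.3) from 1 UMI in these B and T cells summed together, too few to tell. The medians of next over own hashtag, 0.0590 in these B cells and 0.0630 in these T cells, decide nothing because cells with several hashtags had been left out. A difference between genotypes, or between the mice pooled, remains open and may account for the excess, and neither was tested.

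A set of 18 genes, among them Gm26740, Psd3, Gm43305, Slc15a2 and Adamts13, differed between pools in B and T cells alike. Within follicular B-like and naive T-like cells the median log2 ratio in the same direction was 1.73 over 35 values, each 1 gene in 1 comparison and library. For the same values it was 2.29 over all lineage cells. This argues against a different mix of cell classes for these values as a group. Values with too few UMIs in these classes were left out, so it does not cover the whole set. The log2 ratio of day 4 over day 0 within follicular B-like cells was 0.80 against 3.84 for Pclaf in control and 0.44 against 3.38 for Nfil3 in KO, and Birc5, E2f8, Cdca3, Sapcd2 and Kcnk6 had none of these values, so the class mix stays open for these genes. Of the 18 genes, 0 lay within 20 Mb of Il2rb, which argues against DNA flanking the edited locus for those that differed between genotypes. Genes that entered the set only by day 4 over day 0 within a genotype, such as Slc15a2, Pclaf and Birc5, do not bear on this. A strain or colony difference between the pooled mice could account for these values and stays open, untested. For day 4 over day 0 the pools also differed by immunization, which was not told apart from it.

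The secretory list was lower in KO than in control B cells on both days. At day 4 the difference lay in plasma cell-like and cluster 11 cells, since without them the median was 0.0342 (11 of 19 higher), inside the random range of −0.02 to 0.08, against −0.33 with them. Of these only plasma cell-like cells were fewer in KO with an interval that excluded 1, 4 against 12, and the ratio of cluster 11 was 0.871 (0.536 to 1.43). Equal class shares gave −0.11 (3 of 19 higher), below the random range of −0.04 to 0.06. That range holds no error from sampling few cells, and the plasma cell-like means rested on 4 and 12 cells. This value therefore cannot decide on a different mix of classes, and a lower level within these cells also stays open. At day 0 these cells were not fewer in KO, with 6 plasma cell-like cells in each pool and 15 cluster 11 cells in KO against 4 in control. Equal class shares gave −0.29 (2 of 19 higher), below the random range of −0.07 to 0.04. The plasma cell-like means rested on 6 cells in each pool, so this value cannot decide on a different mix of classes either. The median without these cells was not taken at day 0. Within follicular, marginal zone and transitional B-like cells the day 0 medians were −0.07, −0.14 and −0.10, each inside its random range. The cause on either day stays open, untested.

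The share of T-library cluster 14 had a KO over control ratio of 0.379 at day 0 and 1.78 at day 4. In the B library the glycolysis list stood at 0.0845 in KO over control at day 0 and −0.13 at day 4, the latter at −0.06 (7 of 15) with lineage cells alone. Prtn3 stood there at 4.24 and −3.29 on the log2 scale, with 98.7 and 90.2% of the KO UMIs in 1 cell, and Ighg3 at 1.58 and −3.37, with 39.3 and 56.4% of the control UMIs in 1 cell and the day 0 value at −1.24 with doublets kept. In the T library the antigen presentation list stood at 0.24 in KO over control at day 0 and −0.24 at day 4, and the interferon list at 0.26 and −0.0839, while within naive T-like cells the day 4 medians were 0.17 and 0.05. The hemoglobin genes of the T library stood in KO over control at 8.47 and −6.77 for Hbb-bs, 7.43 and −6.77 for Hba-a1, 7.23 and −6.36 for Hbb-bt and 7.27 and −7.58 for Hba-a2 at day 0 and day 4, with 64.9 to 83.9% of the higher pool's UMIs in 1 cell.

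Between control and KO, day 4 over day 0, the interferon list of the B library stood at 0.23 and −0.15. Hbb-bt stood there at −1.27 and 4.12, with 95.5% of the KO day 4 UMIs in 1 cell, and Mpo at a lower bound of 7.09 in control (739 against 0 UMIs) and −1.99 in KO, with 51.4% of the control day 4 and 99.6% of the KO day 0 UMIs in 1 cell. The naive T-like share had day 4 over day 0 ratios of 0.639 in control, between 0.293 and 0.964 under other settings, and 1.20 in KO, which lay below 1 under 4 of them. The hemoglobin genes of the T library stood at 7.07 and −8.16 for Hbb-bs, 6.54 and −7.66 for Hba-a1, 6.43 and −7.17 for Hbb-bt and 6.47 and −8.38 for Hba-a2, and Lyz2 at 5.46 and −2.23. The KO value of Lyz2 had 92.5% of the day 4 UMIs in 1 cell, and was 0.0301 under the hashtag ratio rule and 0.12 with lineage cells alone.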

How the results depend on the processing

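No paired analysis was possible because each group was 1 pool and no label pairs animals across the groups compared. Of 612 alternative values of the 85 answers to a comparison, 573 were labelled the same, 35 moved and 4 reversed. Same meant close to the main value by a rule for each kind of value, such as inside its counting interval. Values with wide intervals could thus hardly move, and share ratios whose interval included 1 could not reverse. Class share ratios kept 453 of 468 values, list medians between groups 880 of 914 and between classes 838 of 881, and named genes 1120 of 1344, with 202 moved and 22 reversed. In each setting a cluster took the class name that most of its cells had in the main results, so part of the agreement of shares was built in. Share ratios of clusters 1 and 8 of both libraries, and of clusters 3 and 5 of the T library, were not tried under other settings. The lineage-only, mean per-cell and list member UMI (both between groups), highest Scrublet score, gene number, resolution, variable gene and list gene settings for group results were chosen after seeing the data. Where values moved or reversed, the cause was not tested, except where a setting's construction gives it. The naive T-like ratios depended on the settings. KO over control at day 4, 1.57, was 1.29 with at most 5% mitochondrial UMIs, 1.28 with doublets kept, 1.30 with at least 500 genes, 1.30 without the highest Scrublet scores, 1.34 with list genes and 1.32 at resolution 0.5. Day 4 over day 0 in control, 0.639, was 0.964 at 5%, 0.893 with doublets kept, 0.833 at resolution 2.0 and 0.293 with 3000 variable genes, and in KO, 1.20, reversed to 0.496 with 3000 variable genes, 0.975 with at least 500 genes, 0.921 without the highest Scrublet scores and 0.878 with list genes. Follicular B-like day 4 over day 0 in control was 0.425 with at least 500 genes. CPM without receptor, ribosomal and mitochondrial genes put Il2rb at 1179, 460.1, 325, 208 and 13.3 CPM in NK or innate-like, regulatory, effector or memory, follicular helper and naive T-like cells, by its smaller total, and the amino acid list of plasma cell-like over follicular B-like cells reversed from −0.38 to 0.44. With doublets kept, Il2rb stood at 690.0, 291, 189 and 13 CPM in NK or innate-like, regulatory, effector or memory and naive T-like cells, 103 CPM in T-library control day 4 cells and in 0% of thinned B cells, and log2 ratios reversed for Ighg2b to 1.05 and Ighg3 to −1.24 in B KO over control at day 0, Ighg2b to −0.52 in B KO day 4 over day 0 and Lyz2 to −0.17 in T KO over control at day 0. Thinned to 1000 UMIs, an Il2rb UMI was found in 27.8, 20.1 and 12.5% of regulatory, effector or memory and follicular helper T-like cells and 0% of B cells, and unthinned in 97.46, 64.2, 51.6, 61.2, 3.77 and 0.208% of NK or innate-like, regulatory, effector or memory, follicular helper, naive T-like and B cells, by depth. The hashtag ratio rule reversed Lyz2 to 0.0301 and Mt1 to 1.20 in T KO day 4 over day 0. Mean per-cell CPM reversed in B KO over control at day 0 the MYC list to 0.0416, the antigen presentation list to −0.00635 and Ighg2c to 0.30, and in B control day 4 over day 0 the BCL2 list to −0.00819. With lineage cells only, Il2rb in the B library was 0 CPM in control and KO day 0 and 0.294 CPM in KO day 4, and reversals in B KO over control at day 0 were the MYC list to 0.0215, the antigen presentation list to −0.00119, Ermap to 0.77, Klf1 to 0.77, Ifitm1 to 4.12, Ear2 to −1.56 and Tnfaip2 to 0.0299, in B KO over control at day 4 Prtn3 to 0.43 and Ccl5 to −2.29, in B control day 4 over day 0 Ccl5 to 1.07, in B KO day 4 over day 0 S100a8 to −4.42, S100a9 to −0.51, Ngp to −0.0291 and Ccl6 to 1.92, in T KO over control at day 0 Car1 to 0.0418 and Ighg2c to −0.44, and in T KO day 4 over day 0 Lyz2 to 0.12. Class shares of whole libraries, meant for cells without hashtags, were not run. Depth limits Il2rb in B cells, where 3 UMIs would stand at 0.515 and 0.526 CPM at day 0.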

Other observations

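None of the values here was tested, and they were taken out after the group values were seen. Within follicular B-like cells alone, interferon genes were higher in KO than in control on both days, with medians of 0.51 (12 of 13 higher, percentile 100) at day 0 and 0.44 (11 of 12, percentile 99.97) at day 4. Marginal zone B-like cells had medians of 0.30 on both days (9 of 10 and 11 of 13), and transitional B-like cells 0.34 (8 of 11) and 0.13. In naive T-like cells the interferon median was 0.59 (10 of 12, percentile 100) at day 0 and 0.05 at day 4, in regulatory T-like cells 0.30 (8 of 11) and 0.07, and in effector or memory CD4 T-like cells 0.06 and −0.09. Secretory genes within follicular B-like cells stood at −0.07 (5 of 19 higher) in KO over control at day 0 and 0.05 at day 4.

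Il2rb in regulatory T-like cells stood at 289, 336, 327 and 303 CPM in control day 0, KO day 0, control day 4 and KO day 4, where cluster 9 held 13 of 77, 21 of 116, 116 of 264 and 121 of 416 of these cells, so the levels also depend on the mix of its clusters. It stood in follicular helper T-like cells at 185, 154, 145 and 146 CPM, and in NK or innate-like T cells at 1156, 831, 746 and 768 CPM. In the B library the 4 Il2rb UMIs of B1-like cells gave 2.84 CPM (0.773 to 7.26) and the 6 of cluster 11 cells 2.59 CPM (0.950 to 5.64).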
